A study of Mus musculus with 14 samples.

How the data were processed

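The series measured gene expression by RNA sequencing in whole uteri of FVB/N mice, WT or labelled HIF2A cKO, at diestrus or estrus. Per the labels, total RNA was purified on columns with a DNase step and libraries were made with an Illumina TruSeq RNA kit. The 14 libraries were placed in 4 groups from their labels, 4 per genotype at diestrus and 3 per genotype at estrus. No label says separate animals, so p-values measure only the spread between these samples, which may be technical. Sequencing batches and dates are not given in the sources used here.

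The authors deposited 1 table of FPKM values (fragments scaled by transcript length and library total), with 31274 gene symbols and 3 decimals. The tools were the aligner TopHat2 2.0.4 and the FPKM estimator Cufflinks 2.0.2, on the mouse build mm10, per the submitters' processing notes. The sources used here name these tools without saying what each was used for. The annotation, the options of these tools and any scaling between libraries are not given in the sources used here. All 14 value columns matched 1 sample each by name. FPKM divides by the transcript length and the total, so a gene that takes many fragments lowers the others, and reads shared between paralogs or overlapping genes cannot be told apart. Of the genes, 8438 were at 0 in all libraries. C3, Col1a1, Col1a2, Col3a1, Eef1a1, Fcgbp and Ltf were at 0 in all libraries of at least 1 group and at a mean of at least 50 FPKM in another. An exact 0 in such genes can be a failed estimate, and these 7 genes were left out after this was seen in the table. They were left out of every comparison in the main fit, also where both groups compared had values. In WT, Ltf stood at 363 ± 397 FPKM (SD) at diestrus and 3725 ± 188 at estrus, and Col1a1 at 946 ± 361 and 305 ± 50.3. The gene lists were tested without these 7 genes.

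Read counts were not used here, so the absolute depth of the libraries is unknown. In FPKM the smallest step of a gene depends on its length and on the depth. Ratios of the lowest values were clear in 20 of 91 pairs of libraries and gave the relative depth, with a largest residual of 0.005 log2. HIF2A cKO diestrus replicate 1 and HIF2A cKO estrus replicate 4 had no clear pair. Without counts no counting error can be given, and low values are the least precise. Coordinates are 1-based from GENCODE M21, on the same build, in which 22557 symbols were found.

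Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. Genes with at least 1 FPKM in at least 3 libraries were kept (14278). The 14 libraries entered 1 fit with a mean per group, a mean-variance trend in eBayes and the Benjamini-Hochberg adjustment at 0.05, since groups of 3 and 4 give a poor estimate of the spread alone. A log2 difference on this scale understates the change of genes of low FPKM. The comparisons were estrus minus diestrus in each genotype, HIF2A cKO minus WT in each stage, and the interaction, the cycle change in HIF2A cKO minus that in WT. Fits of the libraries of a single stage were fixed before the data were examined, but their genes and lists were examined after the result was seen. Epas1 was also tested with an exact two-sided permutation test in each stage. The 39 fixed lists of pathway genes and cell type markers were tested with camera at a preset correlation of 0.01 and adjusted over the lists in each comparison. No camera call held with a correlation estimated from the residuals. The set test fry was an alternative.

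The gene lists, the tests, the naming rule and the other settings were fixed before the data were examined. Epas1, Esr1, Pgr and Hif1a were always named. The rule further took, per comparison, the 5 highest and 5 lowest changes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between groups, leaving out small RNAs and numbered gene models. The overlap condition was not used for the interaction. It also took the 2 largest changes of each core list and the largest of each other list that camera called or that had at least 3 genes past the threshold. Other members of the lists are named as examples and were chosen after their values were seen. Genes that the rule took from lists not described in the text are not printed, and some other results are not reported here.

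The alternatives were other pseudocounts, filters and scalings, fits of the libraries compared alone, eBayes without trend or robust, library weights, the replicate number as a block, each library left out in turn, and a 2-fold minimum. Alternatives chosen after the data were seen kept the 7 genes listed at 0, left out the diestrus libraries numbered 3 or the 2 libraries with the most 45S signal, used the block in the diestrus libraries alone, or repeated the alternatives in each stage alone. The labels give the groups the same replicate numbers without saying what they share. The residuals of the 4 same-number pairs of diestrus libraries correlated at 0.321, 0.115, 0.622 and 0.217, all over 0.1. The numbers may therefore pair the diestrus samples. The main fit did not use them, and the block was an alternative only. Diestrus pairs of unlike number passed 0.1 too. WT replicate 1 correlated with HIF2A cKO replicates 2 and 4 at 0.262 and 0.171. WT replicate 4 correlated with HIF2A cKO replicates 2 and 1 at 0.14 and 0.125. The remaining diestrus pairs ran from -0.454 to 0.057. Residuals sum to 0 within a group, so the pair numbered 3 alone can raise the others. The pairing comes from the data and is uncertain, and over all 19 same-number pairs the correlations ran from -0.135 to 0.622.

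The fit was tested on simulated data with each gene's mean and residual SD from the real fit. The simulated noise was independent between genes and libraries and had the same SD in all groups. Steps were given only to genes above a minimum mean level. The real spread was wider at diestrus than at estrus, so the rates below may not hold for the real data. A step of 1 log2 was recovered in 94, 86.6, 92.5, 86.6 and 70.1% of 67 changed genes for the WT cycle, the HIF2A cKO cycle, the genotypes at diestrus, the genotypes at estrus and the interaction. A step of 0.5 log2 was recovered in 59.7, 49.3, 56.7, 52.2 and 28.4%. Among all genes called there, 2.3, 2.5, 4.6, 8.2 and 7.9% were false, above the nominal 5% for the genotypes at estrus and the interaction. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.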

Results

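Gene expression was measured by RNA sequencing in whole uteri of intact, untreated FVB/N mice aged 2 months. The uterus was taken at diestrus, the phase of the cycle in which progesterone from the corpora lutea dominates, or at estrus, which follows the preovulatory rise of estrogen. Wild-type (WT) mice were set beside mice labelled as a conditional knockout of HIF2A (HIF2A cKO). HIF2A is the oxygen-regulated transcription factor encoded by Epas1. There were 4 WT diestrus, 3 WT estrus, 4 HIF2A cKO diestrus and 3 HIF2A cKO estrus libraries, 14 in all. The values were FPKM per gene symbol and summed to between 437879 and 497688 per library. The number of reads per library was unknown, and the low values gave a relative depth of 1.0 to 1.896 between libraries. Log2 values of libraries of the same group correlated with r from 0.956 to 0.994 across genes. The first principal component held 64.8% of the variance and separated the stages, and the second held 14.7%. The median SD over genes was 0.148 in WT diestrus and 0.166 in HIF2A cKO diestrus on the log2 scale, against 0.084 and 0.076 at estrus.

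**Figure D1:**
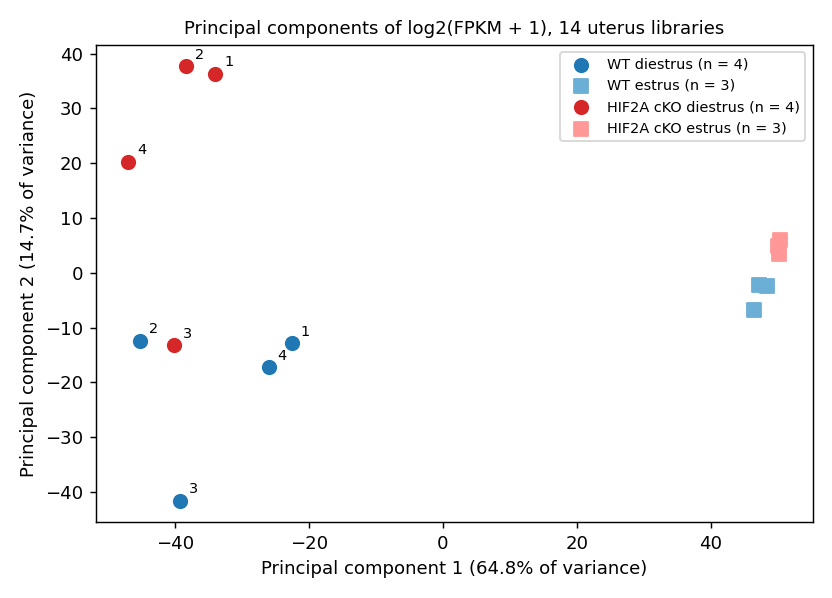
Each point is 1 of the 14 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance on each axis (64.8% and 14.7%). The estrus libraries lie apart from the diestrus libraries on the first component, and the diestrus libraries are spread more widely than the estrus libraries.

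Epas1 (chromosome 17, 86753700 to 86833410, plus strand, mm10) checks the genotype labels, and it was not lower in the libraries labelled HIF2A cKO. At diestrus it stood at 34.8 ± 5.82 FPKM (SD, n = 4) in WT and 39.5 ± 4.44 (n = 4) in HIF2A cKO, with an exact two-sided permutation p of 0.257. This test did not use the replicate numbers. In each same-number pair HIF2A cKO was higher (37.3 against 31.9, 35.1 against 32.7, 45.4 against 43.5 and 40.1 against 31.2). At estrus it stood at 32.9 ± 1.56 (n = 3) in WT and 41.2 ± 4.01 (n = 3) in HIF2A cKO, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. In limma the difference was 0.18 log2 (SE 0.108, adjusted p = 0.227) at diestrus and 0.31 (SE 0.125, adjusted p = 0.605) at estrus. The diestrus difference passed the threshold in limma without WT diestrus replicate 3 (0.29 log2, adjusted p = 0.0391) and without both diestrus libraries numbered 3 (0.22, adjusted p = 0.0427). The estrus difference passed with library weights (0.36, adjusted p = 0.013). In each case HIF2A cKO was higher. An FPKM summed over the whole gene need not fall when some exons are deleted or when deletion is limited to some cells, and the labels name neither the deleted exons nor the Cre line. The genotype is therefore written as the label gives it, and every direction between genotypes below rests on the labels.

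The comparison of estrus with diestrus in WT asked how uterine expression follows the cycle. The largest rises at estrus were of Prap1, Lcn2, Clca3, Arg1 and Aoc1. Lcn2 (chromosome 2, 32384633 to 32388252), an iron-binding antimicrobial protein, rose from 101 ± 115 to 4153 ± 814 FPKM (SD, n = 4 and 3), and Prap1 rose from 27.9 ± 30.3 to 1773 ± 579. Clca3 rose from 24.1 ± 20.2 to 1186 ± 269, Arg1 (arginase) from 1.48 ± 0.554 to 172 ± 34.5, and Aoc1, a diamine oxidase, from 2.98 ± 3.35 to 209 ± 51.9. In the other direction Gli1 (chromosome 10, 127329882 to 127341974), a hedgehog-responsive transcription factor, fell from 57.1 ± 11.1 to 2.25 ± 0.404, Wfdc1 from 92.2 ± 18.5 to 5.02 ± 0.777 and Angptl7 from 133 ± 140 to 5.31 ± 0.452. The gland chemokine Cxcl15 fell from 22.8 ± 13.3 to 0.22 ± 0.0719. In each of these genes the values of the stages did not overlap, as the naming rule required. Their log2 changes ran from 7.10 (Prap1, SE 1.061, adjusted p = 0.000128) to -4.15 (Gli1, SE 0.245, adjusted p = 1.01e-07). The fifth gene at the low end was an unnamed cDNA clone model listed at 0 in all WT estrus libraries.

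Proliferation genes were lower at estrus in WT without exception. All 26 measured cell cycle genes fell, with a median of -2.16 log2, among them Top2a (34.9 ± 3.86 to 2.45 ± 0.372 FPKM) and Ccna2 (20.1 ± 1.64 to 1.39 ± 0.402). The camera adjusted p of this list was 1.14e-15 and was lost with an estimated correlation (adjusted p = 0.384 with an estimated correlation). Of 19 progesterone response genes 14 fell and 1 rose (camera adjusted p = 0.00673; adjusted p = 0.566 with an estimated correlation). Ihh (chromosome 1, 74945315 to 74951672), the epithelial hedgehog ligand induced by progesterone, fell from 23.0 ± 2.96 to 1.61 ± 0.644, the hedgehog receptor Ptch1 fell by 1.82 on the log2 scale, and Sgk1 was the member that rose. Of 21 estrogen response genes 9 rose and 3 fell (camera adjusted p = 0.0534), Lcn2 and Clca3 leading the former and Il17rb (-3.12 log2) and Igf1 (-2.66) falling. Of 29 hypoxia and HIF target genes 16 rose and 3 fell (camera adjusted p = 0.00136; adjusted p = 0.388 with an estimated correlation). The HIF prolyl hydroxylase Egln3 rose from 3.27 ± 0.967 to 30.2 ± 3.26 and Ankrd37 from 0.851 ± 0.167 to 8.36 ± 1.63. Among 9 HIF pathway components 3 rose and 2 fell, with Arnt2 at 1.20 log2 and Hif1a at -0.55. The counts adjusted over the list alone were the same for each of these 5 lists.

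The hormone receptors themselves moved apart. Pgr, the progesterone receptor, fell from 74.5 ± 21.8 to 28.0 ± 2.62 FPKM (-1.34 log2, adjusted p = 2.92e-05), while Esr1, estrogen receptor alpha, stood at 83.8 ± 6.79 and 88.5 ± 5.22 (adjusted p = 0.474). Of 33 nuclear hormone receptors 13 rose and 7 fell (13 and 7 adjusted over the list alone; camera adjusted p = 0.0999). Of 27 chromatin regulators 5 rose and 10 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.876). The latter were led by Uhrf1, a maintenance methylation factor, at -2.41 log2 and included Dnmt1 at -1.16, while the Polycomb methyltransferase Ezh1 rose by 0.91 and its paralog Ezh2 fell by 0.58.

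Matrix and cell type markers also shifted between the stages in WT. Of 22 extracellular matrix genes 14 fell and 4 rose (14 and 4 adjusted over the list alone; camera adjusted p = 0.0534), with Col14a1 falling from 55.4 ± 25 to 8.27 ± 0.846 FPKM. Of 19 matrix remodelling enzymes 12 rose and 3 fell, and Mmp11 went from 34.9 ± 23.4 to 745 ± 45.9 (camera adjusted p = 0.00384; adjusted p = 0.384 with an estimated correlation). Complement genes rose in 11 of 15 cases (Cfb, 25.7 ± 17.0 to 659 ± 112; camera adjusted p = 0.000438), interferon response genes in 12 of 19 (Irf7, 1.94 log2; 0.000279) and macrophage markers in 6 of 8 (0.00145), and none of the 3 lists held a member that fell. Adjusted over the list alone these counts were 11, 12 and 7, and with an estimated correlation the adjusted p was 0.388, 0.485 and 0.384. Of 15 epithelial markers 12 rose (Elf3, 29.4 ± 10.6 to 168 ± 19.8) and of 12 stromal fibroblast markers 10 fell (Vcan, 16.3 ± 3.69 to 2.21 ± 0.27), with camera adjusted p of 0.00136 and 0.0243 (adjusted p = 0.388 for both with an estimated correlation). Adjusted over the list alone, the counts of the matrix enzymes, epithelial and stromal markers were the same.

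In limma, 8161 of 14278 genes (57.2%) differed between the stages in WT, 3287 higher and 4874 lower at estrus, and 1545 of them by at least 2-fold. With median-of-ratios scaling the split was 3984 higher and 3855 lower, 50.8% higher instead of 40.3%.

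In the libraries labelled HIF2A cKO the cycle followed the same course for most genes. Aoc1 rose from 9.22 ± 5.63 to 481 ± 147 FPKM (SD, n = 4 and 3), Prap1 from 20.4 ± 17.3 to 831 ± 72.5, Clca3 from 84.2 ± 73.5 to 2553 ± 721 and Lcn2 from 283 ± 197 to 6298 ± 1500. Dmbt1, a mucosal scavenger protein, rose from 1.10 ± 0.54 to 75.4 ± 8.55, and the matrix metalloproteinase Mmp11 from 19.2 ± 2.86 to 664 ± 59.1. Gli1 fell from 44.1 ± 19.9 to 1.17 ± 0.256, Top2a from 48.5 ± 9.53 to 2.08 ± 0.225, Scube1 from 57.6 ± 14.7 to 2.71 ± 0.253, Ptpn5 from 62.9 ± 24.8 to 2.61 ± 0.462 and Crabp1, a retinoic acid binding protein, from 40.1 ± 19.1 to 1.30 ± 0.376. In each of these genes the values of the stages did not overlap, which the naming rule required of all but Lcn2. The changes of Aoc1 and Gli1 were 5.69 log2 (SE 0.538, adjusted p = 2.41e-06) and -4.30 (SE 0.245, adjusted p = 4.14e-08).

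All 26 cell cycle genes fell here too, with a median of -2.86 log2 (camera adjusted p = 1.72e-15; adjusted p = 0.332 with an estimated correlation). Interferon response genes rose in 18 of 19 cases (Irf7, 2.80 log2; camera adjusted p = 1.86e-07), complement genes in 13 of 15 (Cfb, 4.36 log2; 1.02e-05) and macrophage markers in 7 of 8 (0.000498), with none falling (adjusted p = 0.475, 0.332 and 0.332 with an estimated correlation). Of 29 hypoxia and HIF target genes 17 rose and 5 fell (camera adjusted p = 0.00737; adjusted p = 0.509 with an estimated correlation). Bnip3, a mitophagy receptor, rose from 12.6 ± 1.49 to 45.9 ± 1.95 FPKM, and Vegfa was among those that fell, by 0.61 on the log2 scale. Of 17 circadian clock genes 10 rose and 4 fell here, against 9 and 3 in WT. The camera adjusted p was 0.0149 here and 0.0524 in WT (0.367 and 0.46 with an estimated correlation). Dbp rose by 2.96 log2 here and by 1.89 in WT. In HIF2A cKO Nr1d1 stood at 2.05 and Arntl at -1.34. Progesterone response genes fell in 9 of 19 cases and rose in 2 (camera adjusted p = 0.401), and estrogen response genes rose in 9 of 21 and fell in 6 (camera adjusted p = 0.424). Among 14 unfolded protein response genes 11 fell, led by Hyou1 (-1.33 log2), and 1 rose (camera adjusted p = 0.0885). Among 22 extracellular matrix genes 15 fell, led by Col5a1 at -2.98 log2, and 5 rose (camera adjusted p = 0.0901). Adjusted over the list alone, the counts of these 10 lists were the same as over all genes. Pgr fell by 1.51 on the log2 scale (adjusted p = 6.65e-06), and Esr1 went from 106 ± 8.42 to 82.6 ± 8.23 (-0.35 log2, adjusted p = 0.00462), a call that was lost under quantile normalization (-0.16).

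In limma 8852 genes (62%) differed between the stages in HIF2A cKO, 3640 higher and 5212 lower at estrus, 1964 of them by at least 2-fold. Here too the excess of lower genes depended on the scaling: with median-of-ratios scaling 4376 were higher and 4341 lower, 50.2% higher instead of 41.1%. Across the 14278 genes, which are not independent replicates, the log2 changes in the 2 genotypes correlated with r = 0.875 (Spearman 0.863, jackknife SE of r 0.052). The genotypes shared 2689 genes that rose (838 for independent lists) and 4021 that fell (1779.2), and 25 genes were called in opposite directions. Of the genes called in WT, 96.9% had the same sign in HIF2A cKO.

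**Figure D2:**
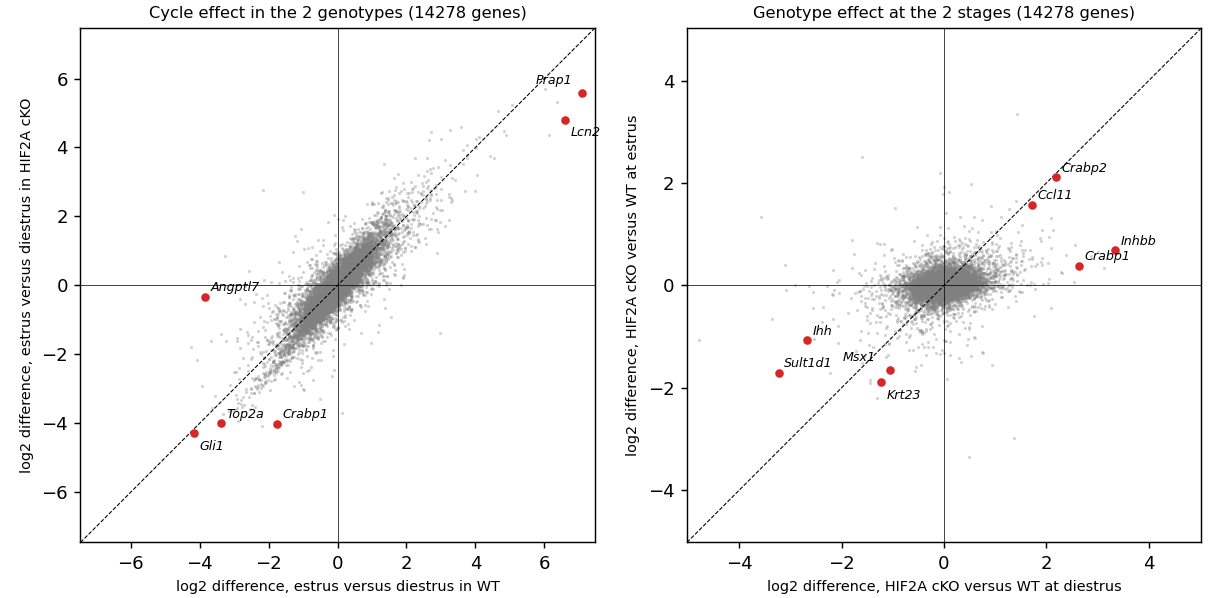
Each point is a gene, with log2 differences on the scale of log2(FPKM + 1) on both axes. One panel sets the change from diestrus to estrus in HIF2A cKO against that in WT (r = 0.875), and the other sets the HIF2A cKO minus WT difference at estrus against that at diestrus (r = 0.308).

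The comparison of the genotypes at diestrus asked what HIF2A deletion changes in that stage, and its directions rest on labels that Epas1 did not bear out. Inhbb (chromosome 1, 119415465 to 119422248), the activin and inhibin beta B subunit, was higher in the libraries labelled HIF2A cKO, at 152 ± 70.7 FPKM against 18.1 ± 19.7 in WT (SD, n = 4 each; 3.34 log2, SE 0.539, adjusted p = 0.00357). Ramp3 (chromosome 11, 6658521 to 6677475), a receptor activity modifying protein, stood at 255 ± 117 against 33.2 ± 23.7, Gadd45g at 153 ± 37.3 against 28.2 ± 16.7, Crabp1 at 40.1 ± 19.1 against 5.14 ± 2.06 and Arg1 at 17.3 ± 13.2 against 1.48 ± 0.554. Ihh was lower, at 5.39 ± 7.81 against 23.0 ± 2.96 (-2.67 log2, adjusted p = 0.00921), as was the gland-enriched sulfotransferase Sult1d1, at 10.8 ± 16.8 against 62.8 ± 33.6 (-3.23 log2, adjusted p = 0.00881). In the 5 higher genes and Ihh the values of the genotypes did not overlap, as the naming rule required. The other 4 genes at the low end were unnamed cDNA clone models, 3 of them listed at 0 in all 4 HIF2A cKO diestrus libraries.

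Progesterone response genes were lower as a group at diestrus in the libraries labelled HIF2A cKO: 10 of 19 fell and none rose (0 and 10 adjusted over the list alone; median -0.67 log2; camera adjusted p = 4.36e-05; adjusted p = 0.687 with an estimated correlation). They included Ihh, Ptch1 (-1.42), the glucocorticoid and progesterone target Zbtb16 (-1.36), Fst (-2.37) and Hoxa10 (-0.81). Of 21 estrogen response genes 6 rose and none fell, with 7 higher adjusted over the list alone (camera adjusted p = 0.00677; adjusted p = 0.687 with an estimated correlation), among them Ramp3, Gadd45g, Padi1 (2.10) and Greb1 (0.87). Of 26 cell cycle genes 14 rose and none fell, with 18 higher adjusted over the list alone (median 0.43 log2; camera adjusted p = 2.94e-07; adjusted p = 0.687 with an estimated correlation), led by the mitotic kinase Plk1 (9.86 ± 1.02 to 20.5 ± 4.08 FPKM) and Cdc20. Hypoxia and HIF target genes were higher in 10 of 29 cases and lower in 2, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.035; adjusted p = 0.687 with an estimated correlation). Angptl4 (1.17 log2), Tfrc (0.76) and the glycolytic genes Eno1 (0.62) and Ldha (0.61) were higher, and Bnip3 (-0.54) and Mxi1 (-0.58) were lower. The camera call of this list was lost among genes of at least 5 FPKM. None of the 9 HIF pathway components passed in limma (0 adjusted over the list alone, 2 at unadjusted p under 0.05). Hif1a stood at 79.7 ± 9.53 against 63.5 ± 16.1 (adjusted p = 0.0848) and passed without WT diestrus replicate 2 (adjusted p = 0.00406) and with library weights (0.000572). The call of Fst ended without WT diestrus replicate 3 (adjusted p = 0.0583) and without HIF2A cKO diestrus replicates 1, 2 and 4 (0.0802, 0.0877 and 0.0545). That of Tfrc ended without WT diestrus replicates 1, 3 and 4 (0.051, 0.068 and 0.0516) and without HIF2A cKO diestrus replicates 1, 2 and 4 (0.0807, 0.0916 and 0.0575). Both were also lost without the 2 libraries with the most 45S signal (Fst, 0.0727; Tfrc, 0.0761).

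Of 14 unfolded protein response genes 4 were higher at diestrus in HIF2A cKO, 6 adjusted over the list alone (camera adjusted p = 0.00609; adjusted p = 0.687 with an estimated correlation and 0.0987 in fry). Of 22 extracellular matrix genes 8 were higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.159), with Col6a3 at 366 ± 143 against 128 ± 48.2 FPKM and Eln at 61.9 ± 21 against 25.2 ± 7.43. Of 23 Wnt pathway genes 8 were lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.168), led by Sfrp2 at -1.68 log2, whose call was lost in the diestrus libraries alone (adjusted p = 0.061). Of 33 nuclear hormone receptors 6 were higher and 6 lower (7 and 8 adjusted over the list alone; camera adjusted p = 0.515), with Nr1h4 (-0.92) and Rarb (-0.88) the lowest. The call of Nr1h4 was lost in the diestrus libraries alone (adjusted p = 0.0712) and in these with the replicate number as a block (0.0692), and that of Rarb in the diestrus libraries alone (0.0997). The call of Rarb also ended without WT diestrus replicates 1 and 4 (adjusted p = 0.0733 and 0.0713) and without HIF2A cKO diestrus replicates 1 and 2 (0.0737 and 0.0799). Esr1 was 0.33 log2 higher (adjusted p = 0.0164, but 0.0541 and 0.0562 without HIF2A cKO diestrus replicates 1 and 2 and 0.0998 under quantile normalization) and Pgr was near its WT level (-0.02, adjusted p = 0.925). Markers of other cells moved in the same comparison: 3 of 15 epithelial markers were higher (Elf3, 1.71; 3 adjusted over the list alone), 3 of 5 mast cell markers were lower (Cpa3, -0.85; 3 adjusted over the list alone), and the 45S ribosomal precursor Rn45s stood at 456 to 578 FPKM in WT but at 223 to 237 in HIF2A cKO, with replicate 4 at 1890.

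In limma 3410 of 14278 genes (23.9%) differed between the genotypes at diestrus, 1976 higher and 1434 lower, 263 by at least 2-fold. This fit shares 1 spread per gene over all groups. The median SD was 0.148 and 0.166 log2 in WT and HIF2A cKO at diestrus, against 0.084 and 0.076 at estrus. The fit therefore tends to favour calls between genotypes at diestrus and to hold them back at estrus. Its counts for the 2 stages should not be set against each other. Fitted on the 8 diestrus libraries alone, whose spread is wider than that at estrus, limma called 430 of 13801 genes (261 higher and 169 lower, 4154 at unadjusted p under 0.05), all among the 3410. With no filter on low values that fit gave 9 genes. Inhbb, Ramp3, Crabp1, Arg1, Gadd45g, Plk1, Cdc20, Eln and Cpa3 were among the 430, while Ihh (adjusted p = 0.0619), Sult1d1 (0.0592), Fst (0.106), Col6a3 (0.0518), Angptl4 (0.0589), Tfrc (0.0958), Sfrp2 (0.061), Elf3 (0.0714) and Esr1 (0.0648) were not. By list, 8 cell cycle genes rose (14 adjusted over the list alone) and 2 estrogen response genes rose (4). Of the progesterone response genes only Nr2f2 fell (6 adjusted over the list alone), Vegfa rose and Bnip3 fell among the HIF targets (9 and 2), and no unfolded protein response gene passed (0). Wnt5a rose and no Wnt gene fell (1 and 4), 2 matrix genes rose and 1 fell (5 and 1), no epithelial marker passed (0), and of the mast cell markers only Cpa3 fell (3). In the fit that called 430, Ptn, a heparin-binding growth factor, was lower (46.5 ± 9.47 against 138 ± 29.0; -1.55 log2, adjusted p = 0.0239), as was the tight junction gene Cldn8 (1.80 ± 1.10 against 7.51 ± 2.29), Atp12a (1.35 ± 0.612 against 5.45 ± 2.09), Msx1os and Atpase6. With the replicate number as a block the diestrus libraries alone gave 2119 genes, including all 430, and with it Ihh, Sult1d1, Fst, Col6a3, Angptl4, Tfrc, Sfrp2, Elf3 and Esr1 passed. The count over all libraries was 7885 with library weights, 1473 without HIF2A cKO diestrus replicate 2, 1753 without replicate 1, 2073 without WT diestrus replicate 1 and 2199 without WT diestrus replicate 4, and rose to 5013 without HIF2A cKO diestrus replicate 3. In the diestrus libraries alone it was 5, 6 and 8 without WT replicates 1, 3 and 4, 8 and 6 without HIF2A cKO replicates 1 and 2, and 1133, 2624 and 953 without WT replicate 2 and HIF2A cKO replicates 3 and 4.

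**Figure D3:**
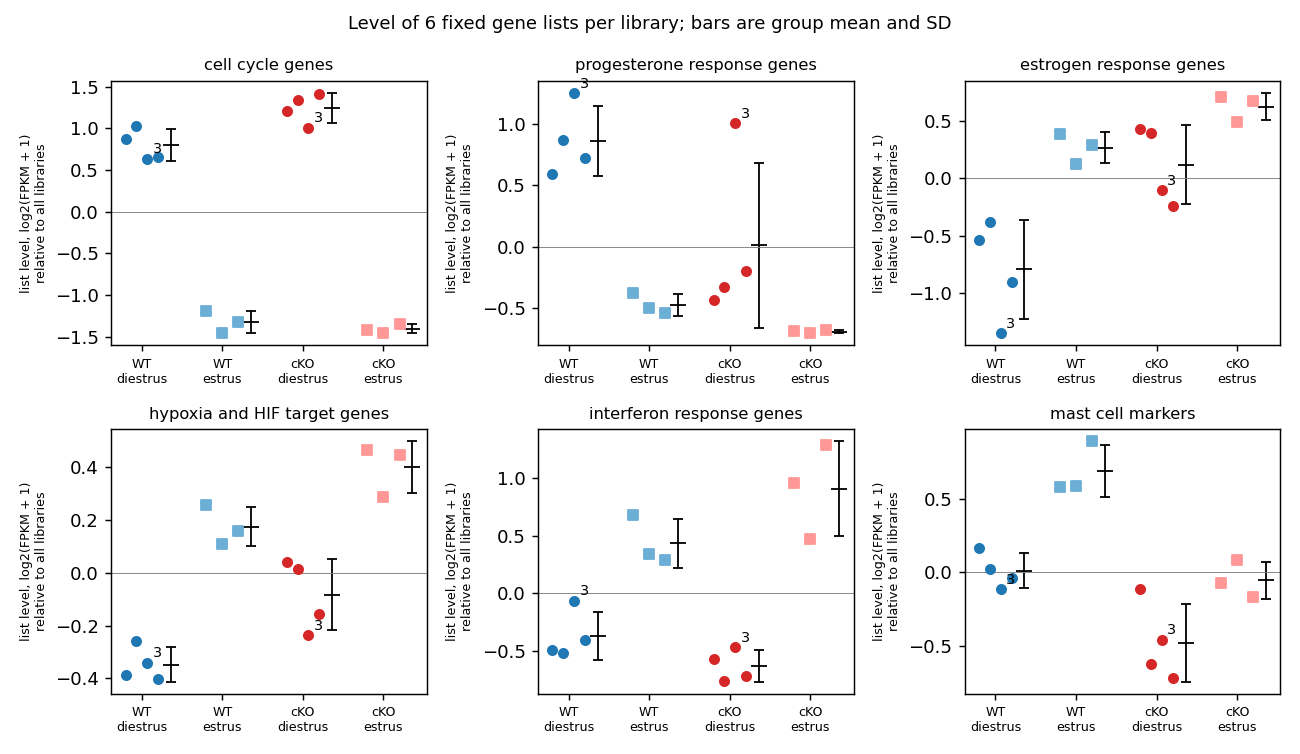
The 14 libraries by group, with the mean log2(FPKM + 1) level of 6 of the fixed gene lists on the vertical axes; libraries numbered 3 are marked. Cell cycle genes lie lower at estrus than at diestrus in both genotypes, and the diestrus libraries numbered 3 lie apart from the others of their group in several lists.

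The comparison of the genotypes at estrus asked the same question in the other stage, and its directions rest on the labels too. The cytokine gene Il1a stood at 5.04 ± 1.91 FPKM in HIF2A cKO against 1.20 ± 0.229 in WT (SD, n = 3 each; 1.42 log2, SE 0.177, adjusted p = 0.00941), and Slc16a3, a lactate transporter, at 14.7 ± 3.43 against 5.10 ± 0.678. Pgm2 was also higher (22.4 ± 1.10 against 15.1 ± 0.729). Lower were Tns4 (5.81 ± 1.62 against 15.8 ± 1.29), Ap3b2 (4.15 ± 0.456 against 11 ± 2.70) and Napepld (5.89 ± 0.556 against 12.3 ± 1.06). In these 6 genes the values of the genotypes did not overlap, as the naming rule required. Esr1 (-0.10 log2, adjusted p = 0.913), Pgr (-0.19, 0.902) and Hif1a (-0.01, 0.998) did not pass. The water channel gene Aqp4, named after its values were seen, was lower as well (-1.32 log2, adjusted p = 0.000381). Its values were low, at 1.493 to 2.335 FPKM in WT estrus and 0.107 to 0.127 in HIF2A cKO estrus. Only the WT estrus libraries reached the filter of 1 FPKM for this gene.

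In limma on all libraries 15 genes differed at estrus, 10 higher and 5 lower, with 1053 at unadjusted p under 0.05; under quantile normalization 13 were higher and 10 lower (56.5% higher instead of 66.7%). Limma on the 6 estrus libraries alone, whose spread is narrower, called 441 of 13526 genes (274 higher and 167 lower, 2887 at unadjusted p under 0.05), among them all 15. The genes named from this fit were chosen after the data were seen, by the same rule with clone models left out. Crabp2 (chromosome 3, 87948666 to 87953376), a retinoic acid binding protein, was higher in HIF2A cKO at 34.3 ± 5.55 FPKM against 7.12 ± 1.02 (2.12 log2, SE 0.132, adjusted p = 0.00195), and the eosinophil chemokine Ccl11 at 33.8 ± 8.35 against 10.6 ± 1.57. Add2, Fam3b and Apobec2 were higher by 1.66, 1.56 and 1.48 log2. The keratin Krt23 (1.24 ± 0.0798 against 7.43 ± 1.66), the homeobox gene Msx1 (chromosome 5, 37820485 to 37824583; 18.0 ± 2.98 against 58.7 ± 7.90; -1.65 log2, adjusted p = 0.00339), Sult1d1 (3.23 ± 0.324 against 13.7 ± 6.35), Gpx2 (3.00 ± 2.04 against 9.97 ± 0.586) and the alarmin Il33 (5.56 ± 1.49 against 16.4 ± 2.14) were lower.

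Hypoxia and HIF target genes were higher at estrus in the libraries labelled HIF2A cKO. The median over the 29 genes was 0.26 log2 (camera adjusted p = 8.47e-07; adjusted p = 0.306 with an estimated correlation), and in the estrus libraries alone 11 rose and none fell, or 15 and 2 adjusted over the list alone. The 11 were Bnip3, Car9, Ddit4, Eno1, Higd1a, Ldha, P4ha1, P4ha2, Pdk1, Pgk1 and Slc2a1, which include glycolytic enzymes, the glucose transporter and collagen prolyl hydroxylases. In the fit of all libraries none of the 29 passed in limma over all genes, 10 rose adjusted over the list alone and 14 had a higher value at unadjusted p under 0.05. The set test fry gave this list an adjusted p of 0.0863. Markers of mast cells, which store histamine and proteases, were lower, with a median of -0.76 log2 over 5 genes, none of which passed in limma on all libraries (3 lower adjusted over the list alone, 4 at unadjusted p under 0.05; camera adjusted p = 4.82e-07; adjusted p = 0.141 with an estimated correlation). In the estrus libraries alone Cma1, Cpa3, Kit and Mcpt4 fell, and all 5 fell adjusted over the list alone. Interferon response genes had a median of 0.46 log2 (camera adjusted p = 9.74e-09; adjusted p = 0.665 with an estimated correlation and 0.393 in fry), with Bst2 the 1 of 19 that passed in the estrus libraries alone (2 adjusted over the list alone). In that fit 3 of 7 uterine gland genes were lower (Foxa2, Lgr5 and Sult1d1; 3 adjusted over the list alone), 7 of 22 extracellular matrix genes were higher and 1 lower (13 and 2 adjusted over the list alone), and Ihh and Msx1 were lower among 15 progesterone response genes (3 lower and 2 higher adjusted over the list alone). Mesothelial markers had a median of 0.36 log2 (camera adjusted p = 0.00215; adjusted p = 0.665 with an estimated correlation and 0.465 in fry), and Msln and Upk3b rose in the estrus libraries alone (5 adjusted over the list alone). No cell cycle gene passed in limma in either fit (0 adjusted over the list alone), with a median of -0.05 log2 over 26 genes and 1 gene at unadjusted p under 0.05 in the fit of all libraries.

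The counts at estrus changed without single libraries. The 15 calls of all libraries became 1 without WT estrus replicate 1, 0 in limma without WT estrus replicate 2 (562 at unadjusted p under 0.05), 1 without HIF2A cKO estrus replicate 1 and 4 without any other estrus library, 5 without WT diestrus replicate 4, 9 without HIF2A cKO diestrus replicate 2 and 29 without HIF2A cKO diestrus replicate 3, and limma called 0 among genes of at least 5 FPKM (771 at unadjusted p under 0.05). The call of Il1a ended without WT estrus replicates 1 and 2 and HIF2A cKO estrus replicate 1 (adjusted p = 0.0521, 0.124 and 0.121) and with pseudocounts 0.1 and 0.01 (0.15 and 0.501). Pseudocount 0.1 also ended the calls of Slc16a3, Tns4 and Ap3b2 (0.0551 each), and pseudocount 0.01 these (0.0823, 0.0823 and 0.0722) and that of Napepld (0.0684). The calls of Slc16a3, Pgm2, Tns4, Ap3b2 and Napepld, in this order, ended without WT estrus replicate 1 (0.142, 0.069, 0.167, 0.192 and 0.167), replicate 2 (0.178, 0.178, 0.178, 0.288 and 0.219) and replicate 4 (0.142, 0.119, 0.131, 0.0572 and 0.11), and without HIF2A cKO estrus replicate 1 (0.304, 0.304, 0.304, 0.347 and 0.304). Without HIF2A cKO estrus replicate 2 those of Pgm2 (0.0842), Tns4 (0.147), Ap3b2 (0.198) and Napepld (0.177) ended, and without replicate 4 those of Slc16a3 (0.175), Pgm2 (0.145), Ap3b2 (0.17) and Napepld (0.154). Diestrus libraries, which enter the same fit, mattered too. Without WT diestrus replicate 4 the calls of Slc16a3, Tns4 and Napepld (0.058 each) and Ap3b2 (0.0707) ended. Those of Tns4 and Napepld (0.0569 each) and Ap3b2 (0.0692) ended without HIF2A cKO diestrus replicate 2, and that of Ap3b2 (0.0611) without WT diestrus replicate 1. HIF2A cKO estrus replicate 1 held Rn45s at 819 FPKM against 208 to 280 in the other estrus libraries. Without it and HIF2A cKO diestrus replicate 4, the libraries with the most 45S signal, 1 of the 15 calls was left and those of all 6 genes ended (Il1a 0.197, Slc16a3 0.352, Pgm2 0.229, Tns4 0.299, Ap3b2 0.352 and Napepld 0.299). The 15 became 1331 with library weights, 63 without both diestrus libraries numbered 3, 26 with no filter, and 7 and 4 with pseudocounts 0.1 and 0.01. The 441 became 57, 234 and 214 without HIF2A cKO estrus replicates 1, 2 and 4, and 81 without WT estrus replicate 2, and were 77 with no filter on low values and 271 with the replicate number as a block.

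**Figure D4:**
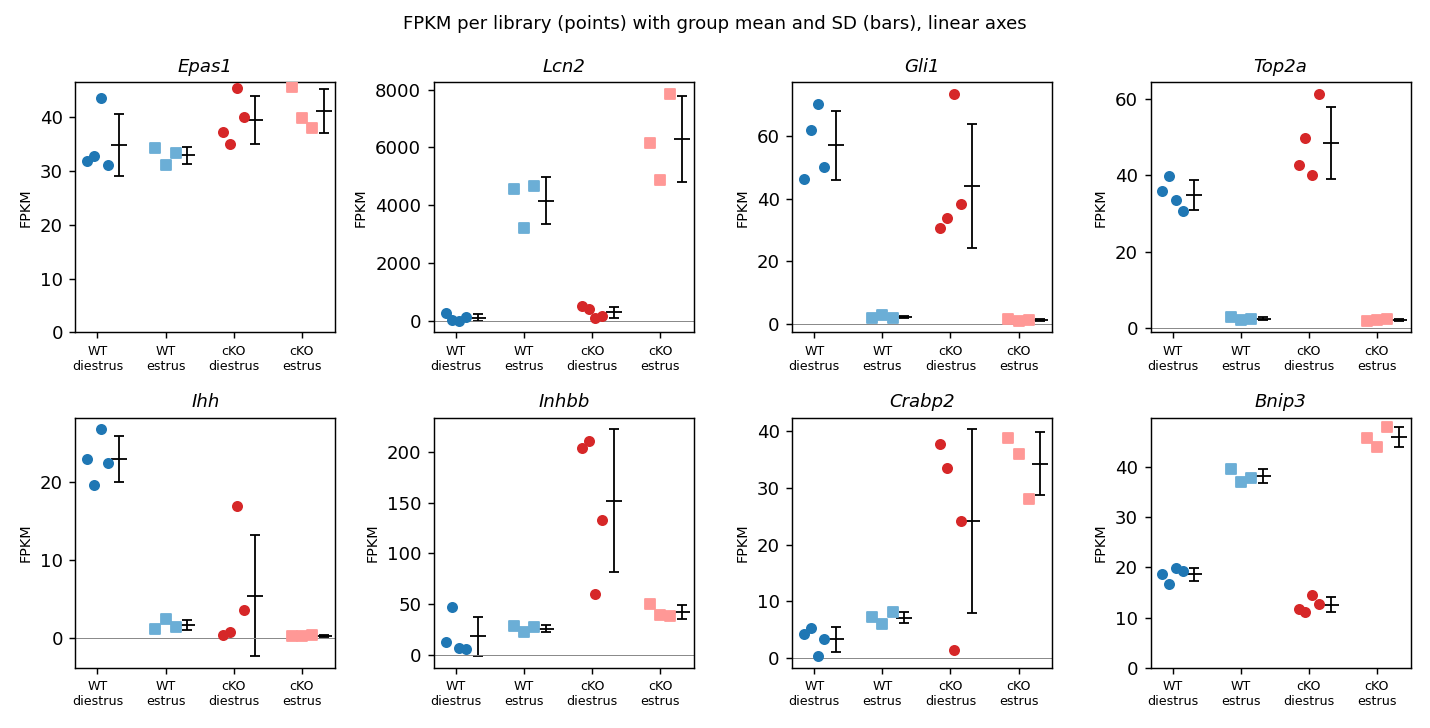
FPKM per library in the 4 groups for Epas1, Lcn2, Gli1, Top2a, Ihh, Inhbb, Crabp2 and Bnip3, with each group's mean and SD. Epas1 is not lower in HIF2A cKO, Lcn2 is higher and Gli1 and Top2a are lower at estrus in both genotypes, and Crabp2 at estrus averages 34.3 in HIF2A cKO against 7.12 in WT.

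Whether the genotype difference itself changed between the stages was tested as an interaction. Bnip3 (chromosome 7, 138890836 to 138909519) was lower in HIF2A cKO than in WT at diestrus (12.6 ± 1.49 against 18.6 ± 1.31 FPKM, n = 4 each) and stood higher at estrus (45.9 ± 1.95 against 38.1 ± 1.40, n = 3 each), an interaction of 0.80 log2 (SE 0.117, adjusted p = 0.0395). Pura (-0.70 log2, adjusted p = 0.015) and Ksr1 (-0.97, adjusted p = 0.0395) were higher in HIF2A cKO at diestrus, at 20.3 ± 0.849 against 13.5 ± 0.239 and 13.5 ± 1.99 against 6.35 ± 0.6, and differed less at estrus. The other 2 of the 5 genes called in limma, Aqp4 and C030046I01Rik, fell outside the naming rule and are named after their values were seen. C030046I01Rik was listed at 0 in all 4 HIF2A cKO diestrus libraries and in WT estrus replicate 4, and 2511 genes had an unadjusted p under 0.05. As groups, cell cycle genes had a lower interaction (median -0.60 log2; camera adjusted p = 6.88e-11) and interferon response genes a higher one (0.71; 1.14e-07), with 16 lower and 6 higher adjusted over the list alone, but with an estimated correlation the adjusted p was 0.822 for both. Progesterone response, complement, mesothelial and clock genes had a higher interaction and unfolded protein response genes a lower one (camera adjusted p = 0.00114, 0.00498, 0.00577, 0.00577 and 0.0312; 0.822 for each with an estimated correlation), and none of these 7 list calls held in fry. Esr1 (-0.43 log2, adjusted p = 0.151) passed without HIF2A cKO diestrus replicate 3 (-0.49, 0.0317) and without both diestrus libraries numbered 3 (-0.44, 0.036). It also passed with the replicate block (0.0465) and with library weights (0.00289). Hif1a (-0.36, 0.387) passed only with library weights (-0.63, 0.00475), and Pgr (-0.17, 0.726) did not pass. The count of 5 was 462 with the replicate number as a block, 5225 with library weights and 1204 without both diestrus libraries numbered 3. It was 1181 without HIF2A cKO diestrus replicate 3, 297 without WT diestrus replicate 2, 26 without HIF2A cKO diestrus replicate 4, 1 without WT diestrus replicate 1 or HIF2A cKO diestrus replicate 2, 2 without WT diestrus replicate 3, WT estrus replicate 1, HIF2A cKO diestrus replicate 1 or HIF2A cKO estrus replicate 2, and 3 without HIF2A cKO estrus replicate 1. Limma called 0 without WT estrus replicate 2 or HIF2A cKO estrus replicate 4 (1977 and 1992 at unadjusted p under 0.05). The calls of Bnip3 and Ksr1 ended without any single library except WT diestrus replicate 2 and HIF2A cKO diestrus replicates 3 and 4 (adjusted p 0.0704 to 0.162 and 0.0692 to 0.165) and with pseudocount 0.01 (0.0533 each), and that of Bnip3 without the 45S libraries (0.0928). That of Pura ended without WT diestrus replicate 1 (0.0584), WT estrus replicate 2 (0.0819), HIF2A cKO diestrus replicate 2 (0.0565) and HIF2A cKO estrus replicates 2 and 4 (0.0632 and 0.0764).

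Across genes, the genotype differences at the 2 stages correlated with r = 0.308 (Spearman 0.282, jackknife SE 0.074), and 72.1% of the genes called at diestrus had the same sign at estrus. Among 13128 genes tested in both single-stage fits, 19 were higher in HIF2A cKO in both (4.3 for independent lists), 5 lower in both (1.8) and 1, Bnip3, was called in opposite directions. Those higher included Inhbb, Ramp3, Bst2, Ccl11, Col6a2, Eln and Rarg, and those lower included Cldn8 and Cpa3. The differences at the 2 stages share no library.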

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

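The splits of the libraries and the tests of the position within diestrus and along the cycle were planned, while the tests of exchanged labels, ribosomal RNA, hormone phase, scaling, cell shares and Hif1a were chosen after the result was seen.

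Some values lay far from the other 3 libraries of their group. Among 235 groups of 4 values, 16 held such a library, 6 of them in HIF2A cKO diestrus replicate 3 and 5 in HIF2A cKO diestrus replicate 4. A share of 5% would give 11.8, if the values were normal and independent. Most were FPKM of genes chosen for their changes, which can vary together, so 11.8 is only a rough reference. In HIF2A cKO diestrus replicate 3, Angptl7 stood at 98.48 FPKM (3.612 to 4.38 in the others), Atp1b1 at 58.16 (13.35 to 17.73), Fst at 9.073 (0.365 to 0.448) and Sult1d1 at 35.93 (1.487 to 3.776). The chaperone gene Hsp90b1 at 269.9 (457.7 to 496) and the transferrin receptor gene Tfrc at 10 (21.54 to 22.6) were low there. In WT diestrus replicate 3, Fst stood at 43.18 (4.129 to 10.08) and Epas1 at 43.51 (31.19 to 32.74). In WT diestrus replicate 2, Ccl11 stood at 15.11 (5.844 to 6.596), Col6a3 at 199.4 (97.48 to 111.3) and Ptpn5 at 42.52 (2.174 to 4.914). In HIF2A cKO diestrus replicate 4, Atpase6 stood at 36.02 (6.469 to 7.68) and an unnamed cDNA clone model at 25.83 (0 to 3.035). In that library the ribosomal precursor Rn45s stood at 1890 (222.7 to 236.8), Mir6236 at 35200 (5236 to 7893), and the 10 highest genes held 11.01% of the total (5.353 to 6.228).

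The genotype difference changed between the stages in 5 genes by the interaction in limma: Bnip3 (0.801 log2), C030046I01Rik (4.910), Aqp4 (-1.318), Ksr1 (-0.971) and Pura (-0.696).

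Other splits of the same libraries bear on the counts. In the cycle comparison, 1 of 35 splits gave as many genes as the labels in WT (8161 against at most 4923 in the others) and 1 of 35 in HIF2A cKO (8852 against 6610). Both shares are under 0.05, and 1 of 35 is the smallest that these splits allow. For the genotypes at diestrus, 2 of 35 splits gave as many (3410 against 3652), and 2 of 35 in the diestrus libraries alone (430 against 1006), so these splits do not exclude chance. The larger split exchanged WT diestrus replicate 2 with HIF2A cKO diestrus replicate 3, so it parts only 2 of the 4 same-number pairs that the labels part, and its count points to a structure of the samples. Among the 8 splits that part all 4 pairs, too few for a share under 0.05, 1 of 8 gave as many with the replicate number as a block: the labels gave 2119 genes, and limma called 0 in each of the others. In these 8 splits the labels also gave 3410 and 430 without the block and each of the others 0. The comparison with these splits was added after the result was seen, and it rests on the uncertain pairing by number. At estrus, 10 splits are too few for a share under 0.05 (15 against at most 1 in the others, and 441 against 1 in the estrus libraries alone, with 1 of 10 splits giving as many in both fits). For the interaction, 4 of 100 splits gave as many, so the share is under 0.05, but the highest of the others called 354 against 5, which points to a structure of the samples.

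The genotype difference at diestrus, with higher estrogen response and cell cycle genes and lower progesterone response genes in the libraries labelled HIF2A cKO, could reflect the genotype, the time within diestrus at which uteri were taken, or exchanged labels. Exchanged labels of WT diestrus replicate 2 and HIF2A cKO diestrus replicate 3 are argued against but not excluded. Of 441 genes called at estrus, 33 separated the same way at diestrus with the labels exchanged and 82 with the labels as given (at most 36 in any other of 70 splits). On the other side, the exchanged split called more genes in limma (3652 against 3410). The 2 libraries also lay close on the second principal component (-12.4 and -13.2). The position within diestrus stays open, because across genes the difference correlated with r = -0.43 with the contrast of the libraries numbered 3 against the others, which holds 18.4% of its variance. The estrus difference hardly followed that contrast (r = -0.067, looked at after the result was seen), so the contrast accounts for little of the agreement between the stages (r = 0.308). The position along the cycle (r = -0.125 with the cycle change) and the genotype itself stay open too, since for the latter no value here parts it from other differences between the groups shared by both stages.

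The diestrus libraries numbered 3 resembled each other across genotypes (r = 0.622 across genes for their contrasts with the others), in cell markers as well as in hormone response genes: as list medians against the others, T and NK cell markers were higher by 1.86 log2 in WT and 1.75 in HIF2A cKO, erythroid markers by 1.72 and 0.79, endothelial markers by 0.75 and 0.53 and gland genes by 0.86 and 1.75, while epithelial markers stood at -0.71 and -1.03. Carried-over ribosomal RNA is argued against, since Rn45s was lowest of its group in WT diestrus replicate 3 but not in HIF2A cKO diestrus replicate 3 (236.8 FPKM), where only replicate 4 was higher. Against an exchanged label of that HIF2A cKO library with a WT library, its score over the genes called at estrus lay 0.142 log2 above the highest WT diestrus library. On the second principal component, however, it stood at -13.2, within the WT diestrus libraries (-12.4 to -41.5). The other HIF2A cKO diestrus libraries stood at 20.3 to 37.7, so an exchange is not excluded. A shared hormone phase within diestrus may account for it and stays open: the estrogen list minus the progesterone list stood at -0.918 log2 or lower in both genotypes. Other cell contents of the tissue pieces would move the markers too, and neither these nor a shared day or batch were tested apart.

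Hypoxia and HIF target genes were higher at estrus in the libraries labelled HIF2A cKO. The list does not part targets of HIF2A from those of other HIF proteins, so its direction cannot be set against a loss of HIF2A. A scaling offset shared by all genes is argued against, if most genes are taken as unchanged. The median over all genes was 0.006 log2 without further scaling and 0.005 with median-of-ratios scaling, which therefore moved little. The list median was 0.262 log2 with that scaling. A changed share of cell types stays open, because among epithelial, stromal, muscle, endothelial and macrophage markers the highest median was 0.161 log2 against 0.263 for the list, whose mean has an SE of 0.071, and outside these 5 types mesothelial markers stood at 0.358 and mast cell markers at -0.762. No rise of Hif1a transcript was seen at estrus, at 41.7 ± 2.88 FPKM in HIF2A cKO against 42.2 ± 3.11 in WT. The difference was -0.015 log2, and its upper bound of 0.306 does not exclude a rise of the list's size. That bound takes its SE from the fit of all libraries, in which the diestrus libraries spread more widely, so it is a loose one. A response of the tissue to the genotype could also give it and was not tested apart.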

How the results depend on the processing

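The fits of each stage alone under every choice, the block in the diestrus libraries alone, the genes listed at 0 kept, and the fits without both diestrus libraries numbered 3 or without the 2 libraries with the most 45S signal were chosen after the data were seen. Of the named genes, 3832 values under an alternative kept direction and side of the threshold, 222 lost the call, 11 gained one and 16 changed sign, and of the lists called by camera 327 kept the call and 78 lost it, 45 of these with an estimated correlation. The cause was not tested. At least 2-fold changes numbered 1545, 1964, 263 and 2 for the WT cycle, the HIF2A cKO cycle, the genotypes at diestrus and the interaction. Genotypes at diestrus (3410): 430 in the diestrus libraries alone, 2119 with the replicate block in these, 7885 with library weights. Genotypes at estrus (15): 7 and 4 with pseudocounts 0.1 and 0.01, 26 with no filter, 0 in limma at FPKM of at least 5 (771 at unadjusted p under 0.05), 23 under quantile normalization, 441 in the estrus libraries alone, 1331 with library weights, 63 without the diestrus libraries numbered 3, 1 without the 45S libraries. Interaction (5): 8 and 2 with pseudocounts 0.1 and 0.01, 11 with no filter, 10 under quantile normalization, 5225 with weights, 462 with the replicate block, 12 with genes at 0 kept, 1204 without the libraries numbered 3, 11 without the 45S libraries. In 1 stage alone, no filter gave 9 at diestrus and 77 at estrus, and the replicate block 2119 and 271. At estrus the same-number pairs correlated at 0.08, 0.096 and -0.047, and 10 of 14 libraries, not all, correlated best with their own number; the block gave 8786, 9468, 4781 and 19 genes for the other comparisons. Among the named genes and the lists called by camera, the block ended 1 list call, of smooth muscle markers at estrus. It ended the gene calls of Napepld (limma adjusted p = 0.0571) and Ap3b2 (0.0754) at estrus. In the diestrus libraries alone it ended those of Cd34 (0.0843), Vegfc (0.0641), Nr1h4 (0.0692) and Cxcl15 (0.0501). Apart from the interaction of Esr1, which passed, it changed no other call among these genes and lists. With library weights Epas1 passed in the HIF2A cKO cycle (0.19 log2, adjusted p = 0.0356). Agreement of the cycle change was 0.815 with pseudocount 0.01 and 0.801 with weights, and of the genotype difference 0.205 with pseudocount 0.01. Leaving out 1 library gave 6959 to 8574 and 7851 to 9052 genes for the cycle in WT and HIF2A cKO, 1473 to 5013 and 0 to 29 for the genotypes at diestrus and estrus, 0 to 1181 for the interaction, and 5 to 2624 and 57 to 446 for the genotypes in each stage alone. Values that changed sign were near 0 and past no threshold: Epas1 in the WT cycle with median-of-ratios (0.023), weights (0.010), block (0.021), without WT diestrus replicate 3 and without both libraries numbered 3 (0.041 each; -0.115 to 0.041 without 1 library); Epas1 in the HIF2A cKO cycle without HIF2A cKO estrus replicate 1 (-0.014) and without the 45S libraries (-0.004; -0.014 to 0.129 without 1 library); Pgr at diestrus with weights (0.102), without WT replicate 2 (0.157), HIF2A cKO replicate 4 or the 45S libraries (0.027 each; -0.141 to 0.157 without 1 library); Hif1a at estrus without WT replicates 2 and 4 (0.021 and 0.010), HIF2A cKO replicates 1 and 4 (0.017 and 0.007) or the 45S libraries (0.017; -0.076 to 0.021 without 1 library). Depth is unknown, so low values limit what can be seen.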

Other observations

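The tests of other lists below were planned, while the fits of a single stage were examined, and the genes near Epas1 counted, after the result was seen. Further gene groups followed the cycle in WT. Of 10 secreted antimicrobial genes 7 rose at estrus and 1 fell (camera adjusted p = 0.0258; adjusted p = 0.485 with an estimated correlation), and the call was lost with no filter and under both other scalings. Of 17 water and ion transport genes 10 rose and 2 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.019; adjusted p = 0.384 with an estimated correlation and 0.0504 with median-of-ratios scaling), with Aqp5, a water channel of secretory epithelia, going from 14.4 ± 9.41 to 47.3 ± 3.78 FPKM (SD, n = 4 and 3). Of 8 MHC class II genes 5 rose, H2-Ab1 by 0.68 log2 (8 adjusted over the list alone; camera adjusted p = 0.00859; adjusted p = 0.485 with an estimated correlation). Among 14 retinoid pathway genes 5 rose and 4 fell (camera adjusted p = 0.503), with Stra6, the retinol transporter, going from 31.8 ± 8.75 to 5.8 ± 2.15. Among 18 angiogenesis genes 3 rose and 7 fell (camera adjusted p = 0.648), with Apln, the apelin ligand, at -1.76 log2. Of 11 smooth muscle markers 1 rose and 5 fell (camera adjusted p = 0.447), and Cnn1 went from 383 ± 60.9 to 165 ± 26. Wnt5a fell by 1.89 on the log2 scale in HIF2A cKO, where among 23 Wnt pathway genes 6 rose and 4 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.475).

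Between the genotypes, Ptgfr, the prostaglandin F receptor, was lower in the libraries labelled HIF2A cKO at diestrus (3.03 ± 1.28 against 8.26 ± 2.53 FPKM, n = 4 each; -1.21 log2, limma adjusted p = 0.00524), in a prostaglandin list with 3 genes higher and 3 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.515). Smarca2, a chromatin remodelling ATPase, was at -0.80 log2 among 27 chromatin regulators, of which 4 were higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.418); its call was lost in the diestrus libraries alone (adjusted p = 0.0564). Clock genes had a median of 0.12 log2 at estrus (camera adjusted p = 0.0342; adjusted p = 0.665 with an estimated correlation, 0.146 among genes of at least 5 FPKM and 0.393 in fry), with Per1 the 1 of 17 that passed in the estrus libraries alone (4 adjusted over the list alone). Estrogen response and matrix genes had medians of 0.25 and 0.20 log2 at estrus (camera adjusted p = 0.0351 for both; adjusted p = 0.665 with an estimated correlation), and both calls were lost under quantile normalization, among genes of at least 5 FPKM and in fry. The genes near Epas1 were counted among those with coordinates that were tested in both single-stage fits. Within 20 Mb, 0 of 85 were called between genotypes in limma in either stage alone. Elsewhere 700 of 12008 were called (5.8%, two-sided Fisher's exact p = 0.00964). The Fisher test takes genes as independent, which neighbours need not be, so a depletion near Epas1 is not established.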
